A study of Mus musculus with 6 samples.

How the data were processed

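Poly-A RNA from sorted cells, in equal number per sample, was sequenced, per the labels' protocols, for 3 AEL and 3 NC samples of mouse bone marrow (strain C57BL/6 per the labels). The authors deposited a single table whose values were whole-number counts per gene, not scaled to a common total, although its name says CPM; library totals were 8541477, 8671615 and 9945330 in AEL replicates 1 to 3 and 8171676, 9037241 and 9385507 in NC replicates 1 to 3. The genome build mm10 and edgeR 3.32.1 are named, with no role, per the submitters' processing notes; the aligner, the counting tool and the strandedness are not given in the sources used here. Every gene in the table exceeded 1 CPM in at least 2 libraries, so a filter of that kind was applied before deposit, and a gene seen in 1 library alone cannot appear. No library repeats another: within NC the chi-square per degree of freedom between libraries was 4.97 to 9.18 and within AEL 49.9 to 62.6. At these totals 3 counts equal 0.302 to 0.367 CPM, the floor used for genes at 0 throughout a group (3 counts in the shallowest library of that group); these floors cover counting error only, and the bootstrap intervals of the chromosome medians cover the spread between genes only.

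The design, its alternatives, the gene lists and the rule for named genes were fixed before the data were examined. That design assumed CPM and limma on log2(CPM + 1), with edgeR's quasi-likelihood test if the values proved to be counts; they were counts, so edgeR 4.0.16 (R 4.3.3) was the main test, with TMM scaling, the group as the only term, genes at 1 CPM or more in at least 3 libraries (12427 of 13007) and Benjamini-Hochberg adjustment at 0.05. Limma 3.58.1 and DESeq2 1.42.0 (26 adjusted p-values NA) were alternatives, with the pseudocount, filter, scaling, robust fit, replicate block and leave-one-out settings given in the closing section. Fold changes are AEL over NC. Their SE is the absolute log2 fold change divided by the square root of the quasi-likelihood F statistic, not a separate estimate. CPM values, as mean ± SD, are counts scaled to library totals multiplied by TMM factors. These factors were 0.925 to 0.949 in NC and 1.04 to 1.10 in AEL. The filter and the floors used the totals alone. Folds against the floor are thus slightly too high for genes at 0 in NC, and are given as about.

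Of the 34 gene lists, 32 had at least 5 measured members and were tested with camera (preset correlation 0.01) on log2 CPM with a prior count of 2, beside camera with an estimated correlation and fry. With the preset correlation 20 lists passed, 2 up and 18 down; with an estimated correlation 0 passed, and fry, which does not compare a list with other genes, called 25. At an unadjusted p under 0.05, camera with an estimated correlation gave 3 lists. The list of mitochondrially encoded genes matched no name in the table, where 13 such genes carry other names and took 2.34% to 2.68% of counts; the sex chromosome list had 4 measured members, of which 0 passed (0 adjusted over the list alone). Medians of lists with genes at 0 in a group, with such genes at their bound, were -6.64 for B cells, -2.97 for immediate early genes, -3.25 for mast cells, basophils and eosinophils and -3.26 for stroma, against fitted medians of -6.71, -3.27, -5.04 and -4.39. The median, mean and test direction differed in sign for the CDK inhibitor, ETS, glycolysis, deacetylase and stress lists, of which none passed.

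Gene names were matched to RefSeq genes of GRCm38.p6, the assembly that mm10 denotes: 12254 by symbol, 475 by synonym and 258 not at all, and 20 rows carry names turned into dates. Of 708 list members 645 were found. The rule for named genes took 13 genes always given, the 8 largest rises and 8 largest falls that separated the groups at a mean of 10 CPM or more in the higher group (without pseudogenes, predicted models, immunoglobulin, T cell receptor and hemoglobin genes), and up to 3 passing members per list. 1 gene that the rule takes is not reported here. Chromosome medians used genes at a mean of 10 CPM or more, with 10000 random gene lists and 2000 bootstrap draws; scripts used Python 3.11.15 with numpy, pandas and matplotlib.

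On simulated counts for AEL versus NC (12427 genes), the test recovered 4% of 50 genes changed 1.5-fold, 4% of 50 changed 2-fold, 74% of 50 changed 4-fold and 84% of 50 changed 8-fold, and called 8 of 30 genes of a set shifted 2-fold, with 6 false calls among 97 in all. That set was recovered by camera and 0 of 30 unchanged sets were called. In a run with 1553 genes changed at each of these folds it recovered 27.0%, 61.1%, 91.4% and 97.0% of them, with 89 false calls among 4389. Both runs gave the groups the same spread for each gene. The real coefficient of biological variation was 44.3% in AEL and 9.02% in NC, so these rates may not hold for the real comparison.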

Results

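RNA sequencing of sorted mouse bone marrow cells compared acute erythroid leukemia (AEL) cells with normal erythroid precursors (NC), to find how gene expression differs in the leukemic cells. Each group had 3 libraries, each from cells sorted in equal number per the labels. The AEL libraries came from GFP-positive cells transduced with ERG, an ETS family transcription factor, and are labelled Trp53-/-, that is, lacking the tumor suppressor p53. The NC libraries came from marrow sorted after staining for CD71, the transferrin receptor, and Ter119, a red cell lineage marker. The groups were thus sorted on different markers, so a difference between them may come from the cells sorted as well as from the leukemia. The source label of all 6 libraries, NC included, also names SETBP1 and ASXL1 mutations, which goes against the wild-type genotype given for NC, and the labels do not settle it. Library totals ran from 8171676 to 9945330 counts over 13007 genes. The labels do not say whether replicates came from separate animals, so p-values measure the spread between these samples.

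The libraries labelled Trp53-/- held more Trp53 counts than the NC libraries. Trp53 (chromosome 11, 69580348 to 69591873, GRCm38) stood at 1172, 1093 and 976 CPM in AEL and at 177, 175 and 162 CPM in NC, a log2 fold change of 2.66 (SE 0.12, edgeR adjusted p = 7.25e-05). Gene-level counts do not show which part of the gene the reads came from, so Trp53 does not check the genotype label. Erg (chromosome 16, 95359169 to 95586600) was at 677 ± 117 CPM (SD, n = 3) in the libraries labelled AEL and at 6.83 ± 2.17 CPM (SD, n = 3) in NC, a log2 fold change of 6.62 (SE 0.30). Reads of an introduced ERG could count toward mouse Erg, and the counts do not separate them. Hdac7, a class IIa histone deacetylase (chromosome 15, 97792661 to 97844502), rose 8.26-fold, with 42.6 to 45.3 CPM in the NC libraries and 318 to 423 CPM in the AEL libraries (edgeR adjusted p = 7.25e-05). Asxl1, a Polycomb-associated chromatin gene, rose by 0.97 on the log2 scale (SE 0.13), and Setbp1 was not analysed here.

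Among the other genes named in advance, Myc, a growth-promoting transcription factor, rose 5.25-fold from 74.0 ± 5.24 to 389 ± 46.1 CPM (SD, n = 3 each). Kit, the stem cell factor receptor, rose by 1.78 on the log2 scale (SE 0.42, adjusted p = 0.0118), and this call ended without NC replicate 3 (adjusted p = 0.0523). Tfrc, which encodes CD71, fell by 1.21 (SE 0.20), and Klf1, an activator of erythroid genes, fell by 0.91 (SE 0.17). Spi1, which encodes the myeloid factor PU.1, fell by 3.79 (SE 0.88), and Ptprc, the pan-leukocyte antigen CD45, fell by 4.27 (SE 0.97). Markers of other leukocytes fell too: neutrophil genes summed to a mean of 526 CPM in AEL and 9833 CPM in NC. Monocyte and macrophage genes summed to 169 and 6279 CPM. The falls of Spi1 and Ptprc thus cannot be told apart from a smaller share of such cells in AEL. Gata1, the central erythroid transcription factor, did not pass, with 310 ± 58.2 CPM in AEL and 407 ± 31.2 CPM in NC (SD, n = 3 each, adjusted p = 0.0702). It passed without AEL replicate 1, with a log2 fold change of -0.49 (adjusted p = 0.0185), and with all libraries by DESeq2 (adjusted p = 0.0472) and without the genes of chromosomes 3, 9, 14, 19 and Y (adjusted p = 0.0463). Epor, the erythropoietin receptor, was at 469 CPM in AEL replicate 1, against 192 and 162 CPM in the other AEL libraries and 288 to 324 CPM in NC. Its log2 fold change of -0.18 (SE 0.39) did not pass and became -0.74 without AEL replicate 1 (adjusted p = 0.00494).

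**Figure D1:**
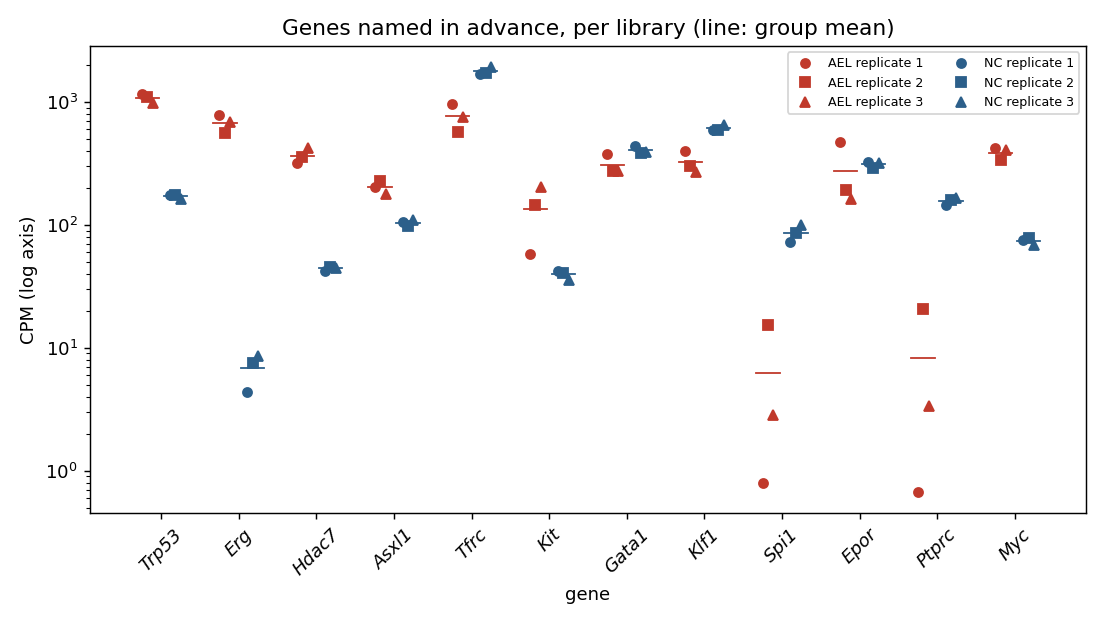
CPM on a log axis of the genes named in advance that the table holds, with 1 point per library (red AEL, blue NC, shape by replicate) and a line at each group mean. Trp53, Erg, Hdac7, Asxl1, Kit and Myc lie higher in all 3 AEL libraries, and Epor is split, with AEL replicate 1 at 469 CPM.

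Of 12427 genes tested, 6563 changed (edgeR quasi-likelihood test, adjusted p under 0.05), 2964 of them higher and 3599 lower in AEL. Single-gene changes are given as log2 fold changes of AEL over NC, unless a fold or CPM is named. At least 2-fold changes numbered 1621 higher and 2696 lower, and at least 8-fold changes 277 higher and 1480 lower. All 3 AEL libraries lay on one side of all 3 NC libraries for 66.0% of genes, where chance gives 10%. The direction split depended on the scaling: higher genes made up 45.2% of those called, 55.2% with library totals alone and 55.5% with quantile normalization, which moved the median log2 fold change of all genes from -0.05 to 0.14 and 0.11. The AEL libraries differed far more from each other than the NC libraries did, with a coefficient of biological variation of 44.3% against 9.02%.

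The genes with the largest rises were scarcely counted in NC. Wt1, a zinc finger transcription factor, was at 57.2, 32.2 and 26.8 CPM in AEL and at 0 in NC, about 106-fold higher against a floor of 3 counts in the shallowest NC library. Car8, Nudt11 and Hey2 were likewise at 0 in every NC library and about 196-fold, 104-fold and 41.6-fold higher against that floor. Cdkn2a, which encodes the cell cycle inhibitors p16 and p19Arf, averaged 144 ± 84.3 CPM in AEL and 0.0384 CPM in NC. Pax6, a developmental transcription factor, averaged 110 ± 32.4 CPM in AEL and 0.0384 CPM in NC. Maats1 and Myom3 differed widely between AEL libraries, from 4.76 to 173 CPM and from 2.82 to 88.1 CPM, and both calls ended when any single NC replicate was left out. The largest falls included genes of tissue macrophages: Spic, a factor of red pulp and marrow macrophages, Timd4, Cd209f and Ms4a7 were at 0 in every AEL library and at least 159-fold, 61.7-fold, 82.5-fold and 59.3-fold lower. Ccr3, the eotaxin receptor, and Adam33 were also at 0 in AEL and at least 342-fold and 194-fold lower, and Itgad and Igf1 each averaged 0.0305 CPM in AEL, against 163 and 70.2 CPM in NC.

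Red cell and iron genes fell broadly, but NC was sorted after staining for CD71 and Ter119, so the sort and the leukemia cannot be told apart here. Of 6 measured hemoglobin genes 4 were lower (4 adjusted over the list alone) and 0 higher, with Hbb-bs at 984 ± 840 CPM in AEL and 15711 ± 1933 CPM in NC (SD, n = 3 each); camera's adjusted p was 0.0306, and adjusted p = 0.509 with an estimated correlation. These genes share nearly identical copies, so counts between them are uncertain. The 4 most abundant took 1.03%, 0.466% and 0.272% of counts in the AEL libraries and 4.42%, 5.07% and 5.54% in NC. Of 18 heme synthesis genes 14 fell (16 adjusted over the list alone), among them Alas2, the first enzyme of the erythroid pathway, at -3.48 (SE 0.72) and Uros at -3.08 (SE 0.16); camera's adjusted p was 2.65e-05, and adjusted p = 0.385 with an estimated correlation. Of 23 red cell membrane genes 16 fell (16 adjusted over the list alone); camera's adjusted p was 0.000174, and adjusted p = 0.472 with an estimated correlation. With quantile normalization 1 member of that list rose. Slc4a1, the band 3 anion exchanger, was at 344, 51.2 and 4.30 CPM in AEL against a mean of 3883 CPM in NC, and its call ended without any single NC replicate. Of 23 late maturation genes 13 fell and 2 rose (13 and 2 adjusted over the list alone): Xpo7, a nuclear exporter of terminal erythropoiesis, fell by 3.81 (SE 0.37) and Bpgm fell by 2.75 (SE 0.25), while Car1, an erythroid carbonic anhydrase, rose 2.69-fold (log2 fold change 1.43, SE 0.14, and 2.44 with quantile normalization). Camera's adjusted p for that list was 0.0119, and adjusted p = 0.509 with an estimated correlation. Of 16 iron genes 9 fell and 2 rose (10 and 2 adjusted over the list alone), with a list median of -0.80. Trf, transferrin, fell 240-fold and Hfe 48.4-fold, well beyond that median, and Aco1, an iron-responsive RNA-binding protein, rose by 1.53 (SE 0.46), or 0.82 without AEL replicate 2. In the camera test the adjusted p was 0.0205, and adjusted p = 0.335 with an estimated correlation. It was 0.0652 without the genes of chromosomes 3, 9, 14, 19 and Y. No member, Aco1 included, was called higher without any single NC replicate. Of 18 erythroid transcription factors 2 rose and 4 fell (2 and 3 adjusted over the list alone), and the list did not pass (adjusted p = 0.578): Bcl11a, a repressor of fetal globin, rose by 1.31 (SE 0.16), and E2f2 fell by 1.79 (SE 0.51), a call that ended without any single NC replicate. The number lower in that list was 7 without AEL replicate 1 and 1 without any single NC replicate, and the number higher was 4 without AEL replicate 3.

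Genes of DNA replication and mitosis fell, and those of the MYC and ribosome biogenesis list rose, while 15 of 39 ribosomal protein genes fell. These differences cannot be told apart from the different sorts of the groups either. Of 32 replication genes 28 fell and 1 rose (28 and 1 adjusted over the list alone). Rrm2, a ribonucleotide reductase subunit, fell by 2.85 (SE 0.16), Tk1 fell by 2.58 (SE 0.36), and Pole, a DNA polymerase, rose by 0.53 (SE 0.13), a call that ended without NC replicate 1 or 2. For the list, camera gave an adjusted p of 4.11e-09, and adjusted p = 0.335 with an estimated correlation. Of 28 mitosis genes 20 fell and 0 rose (20 adjusted over the list alone), such as Ccnb2 at -2.49 (SE 0.25) and Birc5 at -2.15 (SE 0.16); camera's adjusted p was 4.02e-06, and adjusted p = 0.385 with an estimated correlation. Of 22 MYC and ribosome biogenesis genes 20 rose and 1 fell (20 and 1 adjusted over the list alone). Mybbp1a, a nucleolar protein, rose by 2.02 (SE 0.20), and Odc1 fell by 0.69 (SE 0.24), a call lost under several settings, among them median-of-ratios scaling (adjusted p = 0.0545). Camera's adjusted p was 3.19e-07, and adjusted p = 0.385 with an estimated correlation. Of 39 ribosomal protein genes 15 fell and 0 rose (14 adjusted over the list alone), led by Rplp1 at -1.80 (SE 0.31) and Rpsa at -1.56 (SE 0.37); camera's adjusted p was 0.0461, and adjusted p = 0.725 with an estimated correlation. That list did not pass with library totals alone (adjusted p = 0.112) or quantile normalization (adjusted p = 0.124), under both of which 2 members rose, nor without AEL replicate 1 or 3 or NC replicate 1 or 2. It also failed with the replicate block (adjusted p = 0.0564), with limma at pseudocounts of 1 and 5 CPM (adjusted p = 0.0583 and 0.0648) and without the genes of chromosomes 3, 9, 14, 19 and Y (adjusted p = 0.0879). Of 32 nuclear genes of the respiratory chain 21 fell and 0 rose (22 adjusted over the list alone), with Cox7a2 at -1.38 (SE 0.23) and Ndufb8 at -1.33 (SE 0.22); camera's adjusted p was 0.000168, and adjusted p = 0.402 with an estimated correlation. With quantile normalization 1 member rose. Of 21 glycolysis genes 6 rose and 4 fell (6 and 4 adjusted over the list alone, adjusted p = 0.468): Pgk1 rose by 1.88 (SE 0.25), and Ldhb and Hk2 were at -4.39 (SE 0.65) and -4.15 (SE 0.79).

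Markers of several other marrow cell types were lower in AEL, while those of megakaryocytes, given below, went both ways. Of 21 monocyte and macrophage genes 18 fell (18 adjusted over the list alone), led by C1qc and C1qa, complement genes of macrophages, with C1qa at 425 to 470 CPM in the NC libraries and 0.338 to 0.651 CPM in the AEL libraries. The adjusted p from camera was 3.64e-07, and adjusted p = 0.385 with an estimated correlation. AEL replicates 1, 2 and 3 had list medians of -7.81, -4.80 and -5.25. Of 22 neutrophil genes 19 fell (21 adjusted over the list alone), such as Cebpe at -5.77 (SE 0.83) and Fcnb at -5.16 (SE 0.77); camera's adjusted p was 1.74e-05, and adjusted p = 0.509 with an estimated correlation. The number lower was 12, 12 and 11 without NC replicate 1, 2 and 3, and the list's median log2 deviation was -7.61, -2.84 and -5.67 in AEL replicates 1, 2 and 3. All 17 B cell genes fell (17 adjusted over the list alone), including Rag1 at -9.02 (SE 0.62) and Blnk at -7.19 (SE 0.33); camera's adjusted p was 4.11e-09, and adjusted p = 0.282 with an estimated correlation. Of 11 T and NK cell genes 10 fell and 1 rose (10 and 1 adjusted over the list alone): Cd4 fell by 7.71 (SE 0.53) and Lck fell by 7.41 (SE 0.66), and Cd247, a T cell receptor signaling chain, rose by 2.96 (SE 0.44). In the camera test the adjusted p was 0.000409, and adjusted p = 0.385 with an estimated correlation; the number lower was 6 with quantile normalization. Of 11 mast cell, basophil and eosinophil genes 6 fell and 1 rose (6 and 1 adjusted over the list alone), with Epx at 0 in AEL and Il1rl1, the interleukin-33 receptor, up 2.78-fold. For the list, camera gave an adjusted p of 0.0119, and adjusted p = 0.385 with an estimated correlation; it was 0.107 without the shifted chromosomes, and 10 fell without AEL replicate 3. Of 13 stroma and endothelium genes 10 fell (10 adjusted over the list alone), including the collagens Col1a1 and Col3a1; camera's adjusted p was 0.000663, and adjusted p = 0.335 with an estimated correlation. Quantile normalization gave 7 lower and 1 higher there.

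Antigen presentation, interferon and immediate early genes fell as well. Of 18 MHC genes 16 fell (16 adjusted over the list alone), with Cd74 at -5.38 (SE 0.41) and H2-Aa at -5.37 (SE 0.58); camera's adjusted p was 1.01e-06, and adjusted p = 0.371 with an estimated correlation. Of 22 interferon-stimulated genes 13 fell and 1 rose (14 and 1 adjusted over the list alone): Mx1 fell by 5.25 (SE 0.63), Ifit3 went from 8.38 to 0.261 CPM, and Oasl1 rose by 1.33 (SE 0.17). Camera's adjusted p was 0.0015, and adjusted p = 0.466 with an estimated correlation. The list's median log2 deviation was -1.19, -1.26 and -3.18 in AEL replicates 1, 2 and 3. Of 18 immediate early genes, which also respond to cell handling, 15 fell (16 adjusted over the list alone), such as Fos from 231 ± 36.3 to 3.78 ± 1.25 CPM (SD, n = 3 each), while Egr3 was at 0 in AEL; camera's adjusted p was 5.77e-06, and adjusted p = 0.324 with an estimated correlation. The lists of other cell types fell beside these in the same libraries.

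**Figure D2:**
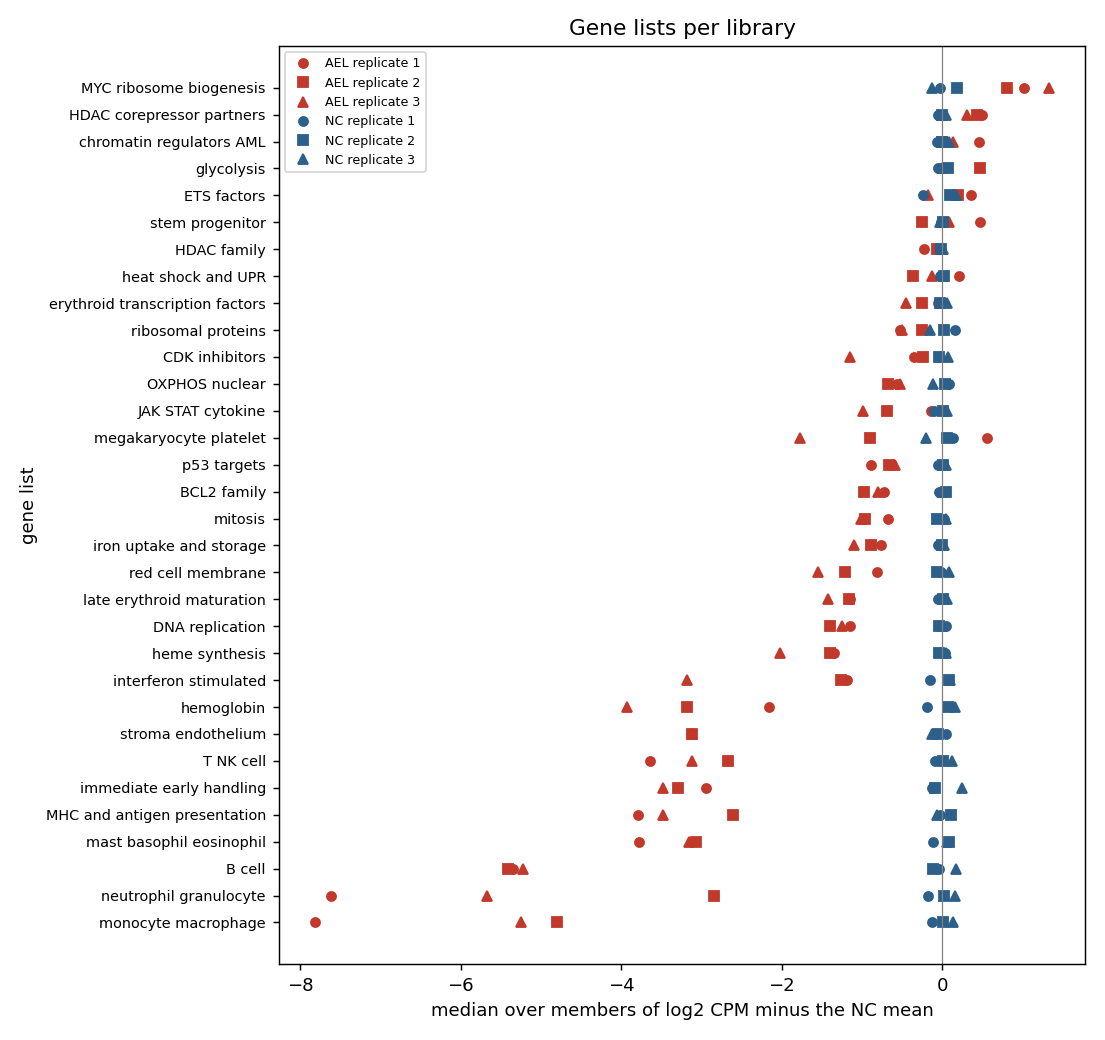
Median over the members of each gene list of log2 CPM minus the NC mean (horizontal axis), for each library (red AEL, blue NC, shape by replicate). The neutrophil list lies at -7.61, -2.84 and -5.67 in the AEL libraries, and the MYC and ribosome biogenesis list at 1.02, 0.81 and 1.33.

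Of 25 p53 target genes 4 rose and 12 fell (4 and 13 adjusted over the list alone), with a list median of -0.96. The list did not pass camera (adjusted p = 0.0817, and 0.385 with an estimated correlation). It passed fry (adjusted p = 0.000357), which does not compare a list with other genes. Cdkn1a, which encodes p21, fell from 5.89 ± 0.419 to 0.553 ± 0.385 CPM, Gdf15 fell by 7.05 (SE 0.59) and Plk2 was at 0 in AEL, at least 13.7-fold lower. Zmat3, an RNA-binding p53 target, rose by 1.90 (SE 0.32). Mdm2, chosen after its values were seen, was at 74.8 ± 5.99 CPM in AEL and 80.4 ± 2.93 CPM in NC (adjusted p = 0.478). Of 8 CDK inhibitors 2 rose and 3 fell (2 and 3 adjusted over the list alone, adjusted p = 0.866): Cdkn2a and Cdkn2b, at 3.77 against 0.203 CPM, rose. Of 15 BCL2 family genes 2 rose and 7 fell (2 and 7 adjusted over the list alone, adjusted p = 0.0578). Bcl2a1b and Bcl2a1a, which share reads as close paralogs, were at -7.58 (SE 0.70) and -5.51 (SE 0.87), the second a call that ended with quantile normalization (-0.66). Bik was at 11.4 CPM in AEL replicate 2 against 3.04 and 3.57 CPM in the others, and its log2 fold change of 1.69 became 0.88 without that library, where the call ended. It was 1.53 to 1.78 without single NC replicates, where the call ended too. With the preset correlation the BCL2 list had a camera adjusted p of 0.0238 to 0.346 over the settings. It passed with no filter, with a filter at 5 CPM and without AEL replicate 3 or NC replicate 1. With an estimated correlation camera gave that list an adjusted p of 0.385. The number higher was 0, 0 and 1 without NC replicate 1, 2 and 3. Of 16 stress response genes 4 rose and 2 fell (4 and 2 adjusted over the list alone, adjusted p = 0.939): Asns, asparagine synthetase, rose by 1.53 (SE 0.31), Dnajb9 fell by 1.29 (SE 0.22), and Trib3 was higher with a call that ended without any single NC replicate. That list had 3 higher and 5 lower without AEL replicate 1, 2 and 2 without any single NC replicate, and 5 and 4 with quantile normalization.

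Histone deacetylase and chromatin genes moved both ways. Of 18 deacetylase genes 4 rose and 5 fell (4 and 5 adjusted over the list alone, adjusted p = 0.806). Library totals alone gave 6 and 3, quantile normalization 5 and 5, and leaving out NC replicate 1 or 3 gave 4 and 3. Hdac7 had the largest rise of the list and Hdac5, another class IIa member, fell by 2.31 (SE 0.47); Hdac4, chosen after its values were seen, was at 38.3 ± 4.06 CPM in AEL and 17.8 ± 1.70 CPM in NC. Of 19 corepressor and MEF2 partners of deacetylases 10 rose and 2 fell (10 and 2 adjusted over the list alone), with Mef2d at 1.24 (SE 0.17) and Bcl6 at -4.27 (SE 0.83). The adjusted p from camera was 0.0245, and adjusted p = 0.385 with an estimated correlation; it was 0.12 with quantile normalization and 0.148 without the shifted chromosomes. Of 21 chromatin regulators 7 rose and 3 fell (7 and 3 adjusted over the list alone, adjusted p = 0.293): Tet2, a DNA demethylase, rose by 1.95 (SE 0.33), and Dnmt3a, a DNA methyltransferase, fell by 3.67 (SE 0.25). Of 20 stem and progenitor genes 8 rose and 4 fell (8 and 4 adjusted over the list alone, adjusted p = 0.297), and the list passed with a filter at 5 CPM (adjusted p = 0.0132). With an estimated correlation and the main filter, camera's adjusted p was 0.466. Slamf1 was at 139, 33.9 and 4.94 CPM in AEL and 0.526 CPM in NC, and Hoxa9 fell by 5.57 (SE 0.89), a call that ended with quantile normalization (-0.74), which left 2 members lower. Of 17 ETS factors 6 rose and 6 fell (7 and 6 adjusted over the list alone, adjusted p = 0.772), from Erg to Spib, which fell by 6.97 (SE 0.30). Of 20 megakaryocyte genes 7 rose and 8 fell (7 and 8 adjusted over the list alone, adjusted p = 0.939): Gp5, a platelet glycoprotein, rose 28.2-fold, and Clec1b fell by 6.17 (SE 0.58) and Ppbp was at 0 in AEL. Of 21 cytokine signaling genes 3 rose and 9 fell (3 and 9 adjusted over the list alone, adjusted p = 0.224): Stat5a rose by 1.95 (SE 0.18), and Socs2 was at -3.47 (SE 0.80), a call that ended with quantile normalization (-0.39), and Il3ra at -3.45 (SE 0.38). Without AEL replicate 3 the number higher in that list was 5.

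Expression of whole chromosomes differed between the AEL libraries. Over 8742 genes, the median log2 ratio to the NC mean, relative to the autosomal median, was -0.72 for chromosome 9 in AEL replicate 1 and -0.75 in replicate 3, -0.71 and -0.74 for chromosome 14 in replicates 2 and 3, -0.89 for chromosome 19 in replicate 3 and 0.56 for chromosome 3 in replicate 2. No random gene list gave as large a median as these (permutation p = 1e-04, the smallest 10000 lists can give; adjusted p = 0.0021 over 126 tests). Smaller shifts also passed. Chromosomes 13 and 18 were raised in all 3 AEL libraries, at 0.17, 0.18 and 0.24 (permutation adjusted p = 0.0244, 0.0244 and 0.0103) and at 0.23, 0.20 and 0.32 (permutation adjusted p = 0.0103, 0.0378 and 0.0056). In single libraries, replicate 2 had chromosome 12 at 0.17 and 7 at -0.14, and replicate 3 had chromosome 12 at 0.27, 3 at 0.25 and 5 at 0.15 (permutation adjusted p from 0.0047 to 0.0434). The autosomal median included the lowered chromosomes, which in replicate 3 raised the values of the others. Part of the smaller shifts there may thus come from the centring. Outside the shifts over 0.3, the AEL medians of the autosomes and X ran from -0.14 to 0.27. The NC medians, each against the other NC libraries and so without any group difference, ran from -0.03 to 0.02 for the autosomes and X. Those of Y, over 4 genes, ran from -0.12 to 0.06. The 4 Y genes Kdm5d, Eif2s3y, Uty and Ddx3y summed in AEL replicate 3 to 5.30% of the NC mean, against 91.9% and 115% in replicates 1 and 2. Within chromosome 9, the 64 genes from Jrkl to Herpud2 (13242790 to 25151813), which include Epor, were higher in AEL replicate 1 than in replicate 2 by a median of 1.27 on the log2 scale, and the 397 genes from Acad8 on were lower by a median of -0.88. Of the genes named above, Epor, Trf, Ccr3, Ccnb2, Cox7a2, Rplp1, Rpsa, Bcl2a1a and Bcl2a1b lie on chromosome 9, Car1, Tet2, Zmat3 and Mef2d on 3, Xpo7, Cebpe, Egr3 and Il3ra on 14, and Blnk, Ndufb8, Ms4a7 and Ifit3 on 19.

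**Figure D3:**
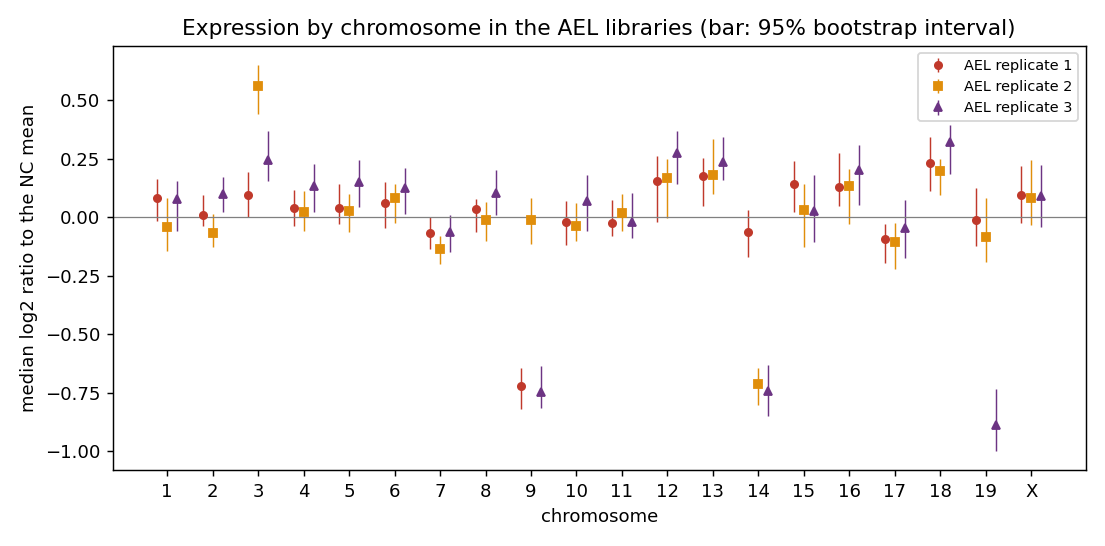
Median log2 ratio of the genes of each chromosome to the NC mean (vertical axis, relative to the autosomal median), for AEL replicates 1 (circles), 2 (squares) and 3 (triangles) with 95% bootstrap intervals over genes. Chromosomes 9, 14 and 19 lie low in some libraries and not in others, as at -0.72, -0.01 and -0.75 for chromosome 9.

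**Figure D4:**
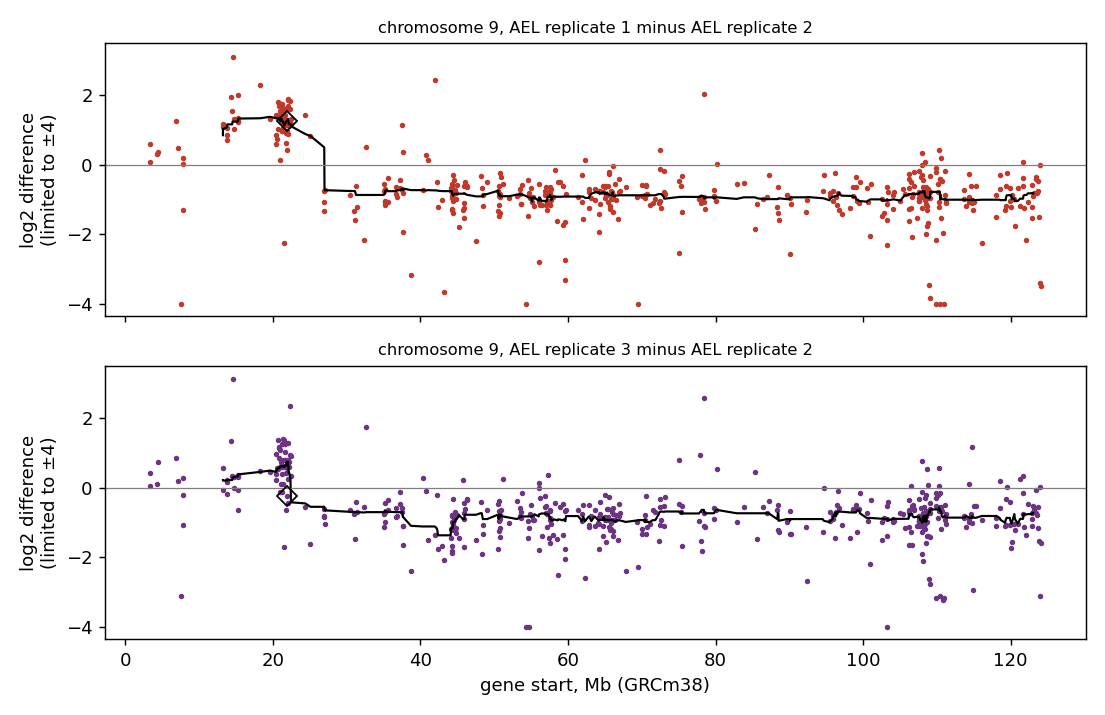
Log2 difference between AEL libraries for each gene along chromosome 9 (points, limited to 4 either way), with a running median of 21 genes as a line and Epor as a diamond. Between replicates 1 and 2 the 64 genes from Jrkl to Herpud2 lie at a median of 1.27 and those from Acad8 on at -0.88.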

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

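The alternatives with library totals alone, voom with group quality weights, and without chromosomes 3, 9, 14, 19 and Y were chosen after seeing the data. Of 99 named genes called, 86 kept their direction and call in each of the 19 settings that held them, and 13 lost it in at least 1. Apart from those always given, these genes were picked for large changes in the same libraries. Their stability thus does not speak for all 6563 calls, and without a single NC replicate 4612 to 4744 genes were called. A filter at 5 CPM held 85 of the 99, and the setting without the shifted chromosomes 79. Over the single genes and settings, 1851 values kept direction and side of the threshold, 45 were weaker, 4 stronger and 2 reversed: Epor, at -0.18 and not passed, ran from -0.74 to 0.10 when 1 library was left out (0.04 without AEL replicate 2, 0.10 without AEL replicate 3). Of the 99, 43 had a log2 fold change smaller by over 1.5 times with quantile normalization, and 40 and 51 with pseudocounts of 1 and 5 CPM. For lists 589 were kept, 14 were weaker and 5 stronger, of which 4 were the BCL2 family list and 1 the stem and progenitor list. Leaving out 1 library gave 1915 to 3375 genes higher and 2662 to 3921 lower, against 2964 and 3599; the genes higher were 1915 without NC replicate 1 and 1972 without NC replicate 2. A 2-fold minimum left 4317 genes and an adjusted p under 0.01 left 4082, both by construction. With an estimated correlation 0 lists passed, against 20; leaving out 1 library gave 19 or 20, and leaving out the shifted chromosomes 16. Library totals alone gave 3800 higher and 3080 lower, quantile normalization 4039 and 3236, DESeq2 3106 and 3760. With the replicate number as a block, 5479 genes changed (2241 higher, 3238 lower) and 19 lists passed. Same-numbered libraries correlated at 0.08, -0.02 and -0.03 in their deviations from the group means, and differently numbered ones at -0.08 to 0.09. These values gave no sign of pairing by number. They do not exclude it, since the wide spread between AEL libraries could hide a shared batch. The planned tests on reads recovered from CPM steps were not run as such, since the table holds counts. In simulation with the same spread in both groups, unlike the real libraries, the test recovered 4% of 2-fold and 84% of 8-fold changes with 50 genes changed at each fold. With 1553 at each fold, nearer to the 52.8% of genes called here, it recovered 27.0% of 1.5-fold, 61.1% of 2-fold and 97.0% of 8-fold changes, so a small change that did not pass is not shown to be absent; how much of this is depth rather than the spread between AEL libraries was not tested.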

Other observations

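The chromosome tests and the tests of explanations in this part were chosen after the result was seen, while the counts of genes and lists, the p53 target list and quantile normalization were planned. A proximal segment of chromosome 9 stood apart from the rest of its chromosome. In AEL replicate 1 its 64 genes lay at a median log2 ratio to NC of 1.28, against -0.10 in replicate 2 and 0.52 in replicate 3, while the 397 genes beyond it lay at -0.88, -0.01 and -0.84. Epor lies inside it, at 469 CPM in replicate 1 and 192 and 162 CPM in the other AEL libraries. Gata2, a progenitor transcription factor picked after its values were seen, was at 461 ± 96.8 CPM in AEL and 10.7 ± 0.355 CPM in NC (SD, n = 3 each), while megakaryocyte genes split the AEL libraries, with list medians of 0.55, -0.90 and -1.77 in replicates 1 to 3.

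The chromosome shifts may reflect copy number change in the leukemic cells. For chromosomes 3, 14 and 19, cut into 5 parts each in the libraries that showed a shift, 20 of 20 parts were shifted in the same direction. So were all parts in 100% of 10000 shuffles of the same genes, so the direction of the parts cannot tell copy number apart from another cause. The size of the shift was not even along chromosome 19 in replicate 3. Its parts lay at -1.18, -1.26, -0.86, -0.37 and -0.54 in order of position. With the ends of the chromosome 9 segment placed on every other gene, 96.8% of the 31 remaining genes in it were higher in replicate 1 than in replicate 2. GC content was argued against for the shifts over 0.5 on chromosomes 3, 9, 14 and 19, the smallest of which was 0.51 after removal of the GC trend. For the smaller shifts the outcome was mixed. Chromosome 13 in replicate 1 went from 0.17 to 0.11 (95% interval -0.01 to 0.19), and chromosome 12 in replicate 2 from 0.17 to 0.11 (-0.03 to 0.22). The other intervals kept the direction of the shift. Chromosomes 3 and 5 in replicate 3 hardly moved, from 0.25 to 0.24 and from 0.15 to 0.16. The centring on all autosomal genes was kept, so its part in these smaller shifts was not removed. The table cannot separate Y loss in replicate 3 from a female donor, since Xist was not analysed here and the deposit's filter would remove a gene seen in 1 library, and DNA copy number was not measured.

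The lower markers of other cell types could come from such cells in the NC sorts, which a tight gate on CD71 and Ter119 would remove. For any marker that normal precursors also express, a lower level in the leukemic cells could be another source. Counts of a whole sort do not show which NC cells held these markers. Of the 66 markers at 10 CPM or more in NC over 6 lists, megakaryocyte genes not among them, 58 (87.9%) were lower. Of the rest, 7 did not pass and Il1rl1 was higher. Both explanations would lower such markers, so this count could not decide between them. Over 20 neutrophil markers the AEL replicate 2 level was a median of 14.3% of NC, with an SD of the log2 ratio of 0.699 against a median of 1.40 in 10000 random lists matched on NC level, of which 0.78% were smaller, but 6 of 23 other fixed lists spread less, so a smaller share of granulocytes cannot be told apart from a program lowered as a whole. Scaling shifted the median log2 fold change of all genes by at most 0.19, and single lists by more. It is argued against for B cells, monocytes and neutrophils, with a highest list median of -3.22 over 4 scalings. For T and NK cells, mast cells and stroma its part cannot be told apart, since quantile normalization gave -0.81, -1.14 and -1.45, against -1.84, -1.43 and -1.97 with the same pseudocount and TMM. Among the abundant macrophage genes, C1qa was at 450 CPM in NC, where the cells that held it were not identified. Whether leukemic and normal erythroid cells differ in such genes was not tested.

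Trp53 was higher in the libraries labelled Trp53-/-. A swap of the groups is argued against by Erg, 6.62 higher on the log2 scale in AEL. A gain of the region is argued against by the 24 genes around Trp53, with a median of -0.13 (quartiles -0.80 and 0.42), and reads of the antisense neighbor Wrap53 by its 53.1 CPM in AEL against an excess of 909 CPM. Transcription from an altered allele or a construct cannot be told apart from an intact gene, since counts per gene do not show which exons are covered. The p53 target list does not settle it, with an adjusted p of 0.0817 by camera and 0.000357 by fry.

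Too few splits of the 6 libraries exist, 10, for a share under 0.05. The real split gave 6563 changed genes, 2964 higher and 3599 lower, and it was 1 of 10 as large in each count, with a highest of 0 genes in the others by edgeR (36 to 93 genes at an unadjusted p under 0.05, against 7369 in the real split). Every other split had AEL and NC libraries on both sides. The difference between the groups thus widened the spread within each side, so few calls could follow there. For lists it gave 20, again 1 of 10, but other splits gave up to 16, so the number of lists alone carries little.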
